A study of Mus musculus with 46 samples.

How the data were processed

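RNA was sequenced from 46 mouse samples of the FVB strain: 11 control livers, 16 liver tumours driven by a Myc transgene (Myc tumours), 8 such tumours taken 16 hours after the transgene was switched off (Myc-off tumours) and 11 tumours driven by a Myc transgene with the V394D substitution (MycVD tumours). Per the labels' protocols, total RNA was depleted of ribosomal RNA with the Ribozero kit, and libraries were made with the TruSeq RNA v2 kit, which does not mark strand. Reads of a gene and of an overlapping antisense gene can therefore not be told apart.

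The deposited table holds exonic RPKM values (eRPKM) made by the authors, as its name and values show, for 21671 genes in 46 columns that match the sample titles. TopHat, TopHat2 version 2.0.8 and the mouse build mm9 are named per the submitters' processing notes. The read counter, the annotation, the treatment of duplicate and multiply mapped reads and the denominator of the RPKM values are not given in the sources used here. Gene symbols were used as in the table, and no coordinates are given because the reference at hand is of another build. Genes with near-identical copies, such as the Mup, Ces, Cyp, Ugt, Saa and Bex families, are uncertain, since it is not known how their shared reads were divided.

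Low values of each gene were whole multiples of a smallest step, which gave the length of 18790 genes and the relative depth of the libraries. Over these genes 100.0% of the values above 0 were whole reads within a tolerance of 0.001. The recovered totals ran from 3.25 to 12.6 M reads per library. The values pointed to a ceiling of reads per kb: Eef1a1, one of the most abundant transcripts, had 1364 to 1703 reads per kb in all libraries, a 1.249-fold range over a 3.892-fold range of depth, while its eRPKM ran from 119 to 426. Over genes longer than 500 bp the highest value per library was 1461 to 2182 reads per kb, the last in control ID125322. Such a ceiling is what collapsing reads with the same start position would give, at most 2000 per kb over both strands, a limit that control ID125322 exceeds. This step was inferred from the values alone and is not given in the sources used here. It compresses differences of abundant genes and lowers their eRPKM in deep libraries, and 1480 genes had a mean over 400 reads per kb. Alb had the highest eRPKM of genes over 500 bp in control ID128990, at 247 (1650 reads per kb). In Myc-off ID151964 Alb averaged 194 and Afp 186 eRPKM, where the highest such values of its libraries were 218 and 224. Comparisons of both genes are limited in this way. Other abundant genes can be affected too: Odc1 was at 121 eRPKM in the shallowest Myc tumour library (7.27 M reads) and at 84.6 in the deepest (12.6 M). In 8 libraries Gapdh was under 30 eRPKM, apart from the rest.

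The sample titles carry an ID, and tumours lettered A to D share it. IDs were taken as animals, which is an assumption, so that the replicate is the animal ID: 11 control, 7 Myc tumour, 3 Myc-off and 10 MycVD IDs, 31 in all. Values of tumours with the same ID were averaged. No 2 libraries of a group agreed within sampling noise (lowest chi-square per degree of freedom 3.39). Replicate numbers pair no samples across groups. Xist and Y-linked genes put 16 IDs as female and 15 as male, mixed within every group. The Myc-off IDs are all numbered above those of the other groups, so a difference in date or batch between them and the other groups cannot be told apart from the switch-off. All MycVD IDs are likewise numbered above all Myc tumour IDs, so a difference in date or batch cannot be told apart from the substitution.

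Genes with at least 1 eRPKM in at least 3 IDs were kept, which left 14566 genes and removed 7105. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with trend, two-sided) on log2(eRPKM + 0.5), with all 4 groups in 1 fit and no covariate, and adjusted by the Benjamini-Hochberg method at 0.05. Fold changes are on this log2 scale, which understates the change of low genes. All adjusted p-values in the text are from limma. The 35 gene lists, of pathways, gene families and cell type markers, were tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over 175 tests, and again with an estimated correlation. Beside each list stands the number of members past the threshold over all genes and that adjusted over the list alone. No list test passed with an estimated correlation.

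The comparisons, the tests, the gene lists, the rule for named genes and the first set of alternatives were fixed before the data were examined. The named genes were Myc, Max, Zbtb17, Odc1, Ncl, Cdkn1a, Cdkn2b, Alb, Afp and Mki67 in every comparison. To these were added the 5 largest rises and 5 largest falls per comparison among called genes whose ID means did not overlap between the groups and whose higher group averaged at least 5 eRPKM, leaving out provisional and small RNA names by their first or last letters. The latter also left out every name that begins with Rn, and did not catch AF357359 and AF357355, whose function is not given here. For each list described, the 2 called members with the largest change in the direction of most called members were named, with the largest called member of the opposite direction. For each overlap of calls the 5 genes with the largest smaller change were named. A gene that these rules chose is not reported here. The choice of lists to describe was made after the list results and a first round of alternatives had been seen.

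On simulated data with 67 genes changed by a log2 fold of 0.5, 67 by 1 and 66 by 2 among 14566, the Myc tumour against control liver fit recovered 70.1%, 92.5% and 98.5%, with 6 false calls. Recovery was 41.8%, 79.1% and 98.5% with 11 false calls for Myc-off against Myc tumours, and 67.2%, 94.0% and 98.5% with 7 for MycVD against Myc tumours. It was 70.1%, 95.5% and 98.5% with 7 for MycVD tumours against control liver, and 46.3%, 88.1% and 98.5% with 9 for Myc-off tumours against control liver. A simulated list of 30 genes shifted by 0.5 was called in 20 of 20 data sets of the Myc tumour against control liver design, and an unshifted one in 1 of 20. These genes were drawn independently of each other, and a list was called at an unadjusted p under 0.05 from camera. The real lists hold genes that vary together, so this does not give the rate of false calls among them.

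The alternatives were every tumour as its own sample with or without the animal ID as a random block, median-ratio and quantile scaling, pseudocounts of 0.1 and 1, no filter and a filter at 5 eRPKM, a fit of the 2 groups compared, array weights, a robust fit, a sex term, a 2-fold minimum, the 6 control IDs from ID125319 to ID128994, which lie within or next to the ID range of the Myc tumours, and leaving out each ID. After seeing the data, 7 more were added: a correction for reads lost at shared start positions, genes under 400 reads per kb alone, limma's voom on the recovered reads, leaving out the 8 libraries with low Gapdh, a term for these libraries, leaving out the shallowest Myc-off library, and a term for depth. For overlaps of calls that share a group, the expected counts were taken from 20 simulated data sets with no effect, from independent lists, and from splitting the shared IDs between the comparisons. With no effect almost no gene is called in either comparison, so a simulated overlap of about 0 was fixed in advance and is no measure of the size of an overlap. Split fits had fewer IDs per comparison, so their counts also fall through lost power. Regroupings of the animal IDs were drawn 100 times.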

Results

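Gene expression was measured by RNA sequencing in normal mouse liver and in liver tumours with a doxycycline-controlled Myc transgene. In these mice the transactivator LAP-tTA turns the transgene on in liver cells from before birth, and doxycycline in the food turns it off. Control liver gave 11 libraries from 11 animal IDs, Myc tumours 16 libraries from 7, Myc-off tumours, taken after 16 hours of doxycycline, 8 libraries from 3, and MycVD tumours 11 libraries from 10. MycVD carries the V394D substitution, which is known to weaken the binding of Myc to Miz1, the transcription factor encoded by Zbtb17. Recovered depth was 5.63 to 8.95 M reads per control library (median 7.32), 7.27 to 12.6 for Myc tumours (median 9.65), 3.25 to 10.4 for Myc-off tumours (median 7.14) and 6.18 to 10.6 for MycVD tumours (median 7.81). The table's Myc gene lay at 1.46 to 18.2 eRPKM in control libraries, 5.41 to 11.1 in Myc tumours, 2.65 to 11.6 in Myc-off tumours and 2.67 to 9.86 in MycVD tumours. The species of the transgene is not stated, so these values do not check the labels.

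Myc tumours were compared with control liver to describe an established Myc-driven tumour. Mki67, a marker of cycling cells, averaged 93.8 ± 9.17 eRPKM in Myc tumours (SD, n = 7 animal IDs) and 3.22 ± 2.09 in control liver (n = 11), a log2 fold change of 4.84 ± 0.22 (SE, adjusted p = 1.1e-18). Ncl, which encodes the nucleolar protein nucleolin, rose by 1.36 ± 0.06 (adjusted p = 1.3e-18), and Odc1, a classical Myc target that encodes the first enzyme of polyamine synthesis, rose by 0.69 ± 0.07 (adjusted p = 2.5e-10). Afp, the gene of the fetal serum protein alpha-fetoprotein, rose by 2.85 ± 0.15 (adjusted p = 5.9e-17), while the albumin gene Alb was at 101 ± 26.02 eRPKM against 209 ± 59.5, a log2 fold change of -1.04 ± 0.18 (adjusted p = 6.0e-06). Alb lay near the read ceiling in some control IDs, which limits the size of this change. In all, 11640 of 14566 genes passed the threshold, 7278 higher and 4362 lower, and 5406 of them changed at least 2-fold.

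Among the largest rises with no overlap between the ID means of the groups were AF357359 at 7.38 ± 0.62, the MAP kinase phosphatase gene Dusp9 at 6.54 ± 0.20, the gamma-glutamyltransferase gene Ggt1 at 6.53 ± 0.15, the imprinted gene Peg10 at 6.40 ± 0.46 and Ccnb1ip1, which encodes a ubiquitin ligase of meiosis, at 6.34 ± 0.23. The largest such falls were the carboxylesterase genes Ces3b at -7.78 ± 0.42 and Ces1f at -7.50 ± 0.37, the anion transporter gene Slco1a1 at -7.35 ± 0.52, Dio1, which encodes an enzyme that activates thyroid hormone, at -7.22 ± 0.41 and the major urinary protein gene Mup3 at -7.16 ± 0.64. Max, which encodes the obligate partner of Myc, rose by 1.20 ± 0.09 (adjusted p = 3.2e-13), and the cell cycle inhibitor gene Cdkn1a rose by 3.42 ± 0.32 (adjusted p = 3.9e-11). The related gene Cdkn2b stood at 0.30 ± 0.21 (adjusted p = 0.18), or -0.02 with quantile normalisation. Zbtb17 stood at 0.35 ± 0.11 (adjusted p = 5.2e-03), but at -0.04 with quantile normalisation and at -0.07 with a depth term. The Myc gene of the table stood at 0.59 ± 0.34 (adjusted p = 0.11), passed the threshold with every tumour as its own sample, and stood at 0.77 (adjusted p = 0.026) without control ID128993, the control with 18.2 eRPKM.

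The groups of genes needed for growth and division were higher in Myc tumours. All 30 tested mitosis genes rose, with a median log2 fold change of 4.74 (30 adjusted over the list alone, limma's camera adjusted p = 7.7e-16; adjusted p = 0.22 with an estimated correlation). The cyclin gene Ccnb1 at 5.79 ± 0.23 and the spindle checkpoint gene Bub1b at 5.54 ± 0.15 led the list. Of 35 DNA replication genes 34 rose and 0 fell, with a median of 2.66 (34 and 0 adjusted over the list alone, adjusted p = 8.4e-10; adjusted p = 0.30 with an estimated correlation). The replicative helicase genes Mcm6 at 4.49 ± 0.31 and Gins2 at 4.37 ± 0.29 led the list. All 53 ribosome biogenesis genes rose, 52 of them under median-ratio scaling, with a median of 1.60 (53 adjusted over the list alone, adjusted p = 5.0e-14; adjusted p = 0.23 with an estimated correlation). The nucleolar genes Rrp1b at 3.48 ± 0.09 and Nle1 at 2.66 ± 0.13 led the list. Of 31 known Myc-activated genes 23 rose and 1 fell, with a median of 0.80 (23 and 1 adjusted over the list alone, adjusted p = 5.7e-04; adjusted p = 0.32 with an estimated correlation). Rcc1, which encodes the exchange factor of the Ran GTPase, rose by 2.81 ± 0.10 and the phosphatase gene Cdc25a by 2.77 ± 0.08, while the cyclin gene Ccnd2 was at -0.43 ± 0.13. Of 21 fetal liver and liver tumour genes 16 rose and 1 fell, with a median of 2.85 (16 and 1 adjusted over the list alone, adjusted p = 4.5e-03; adjusted p = 0.28 with an estimated correlation). Bex2 and Bex1 rose by 6.27 ± 0.21 and 6.09 ± 0.21, and the RNA-binding protein gene Igf2bp2 was at -0.82 ± 0.21. In the same tumours 11 of 12 erythroid genes rose and 0 fell, with a median of 2.50 (11 and 0 adjusted over the list alone, adjusted p = 0.078; adjusted p = 0.71 with an estimated correlation), and which cells carried the transcripts of dividing cells was not tested.

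Genes of mature hepatocytes were lower in the same tumours. All 31 tested drug metabolism genes fell, with a median log2 fold change of -3.46 (31 adjusted over the list alone, limma's camera adjusted p = 5.0e-14; adjusted p = 0.22 with an estimated correlation). The carboxylesterase gene Ces3a at -6.95 ± 0.55 and the glycosyltransferase gene Ugt3a2 at -6.90 ± 0.38 led the list. All 18 genes of bile acid synthesis and transport fell, with a median of -2.41 (18 adjusted over the list alone, adjusted p = 1.7e-09; adjusted p = 0.22 with an estimated correlation). Slco1a1 and Cyp8b1, which encodes an enzyme of cholic acid synthesis, at -5.78 ± 0.46 led the list. All 35 plasma protein genes fell, 32 of them under quantile normalisation, with a median of -1.04 (35 adjusted over the list alone, adjusted p = 2.6e-13; adjusted p = 0.23 with an estimated correlation). The complement gene C9 at -5.56 ± 0.33 and Azgp1, which encodes zinc-alpha2-glycoprotein, at -5.39 ± 0.58 led the list. Of 16 endothelial markers 12 fell and 0 rose, with a median of -1.81 (12 and 0 adjusted over the list alone, adjusted p = 4.1e-05; adjusted p = 0.33 with an estimated correlation). Clec4g, a lectin gene of liver sinusoids, at -4.97 ± 0.48 and Oit3 at -3.26 ± 0.29 led the list. Of 16 genes reported as repressed by Myc with Miz1, 5 rose and 5 fell; the median was 0.15 and turned to -0.09 under median-ratio scaling, and the mean was 0.44 while the list test pointed down (5 and 5 adjusted over the list alone, adjusted p = 0.64; adjusted p = 0.76 with an estimated correlation). The cell cycle inhibitor genes Cdkn1c and Cdkn1a rose by 4.09 ± 0.24 and 3.42 ± 0.32, and the chaperone gene Clu was at -3.18 ± 0.30. The median of all genes was 0.27 and moved to 0.04 under median-ratio scaling, where 51.5% of 11575 calls were higher, against 62.5% as deposited.

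**Figure D1:**
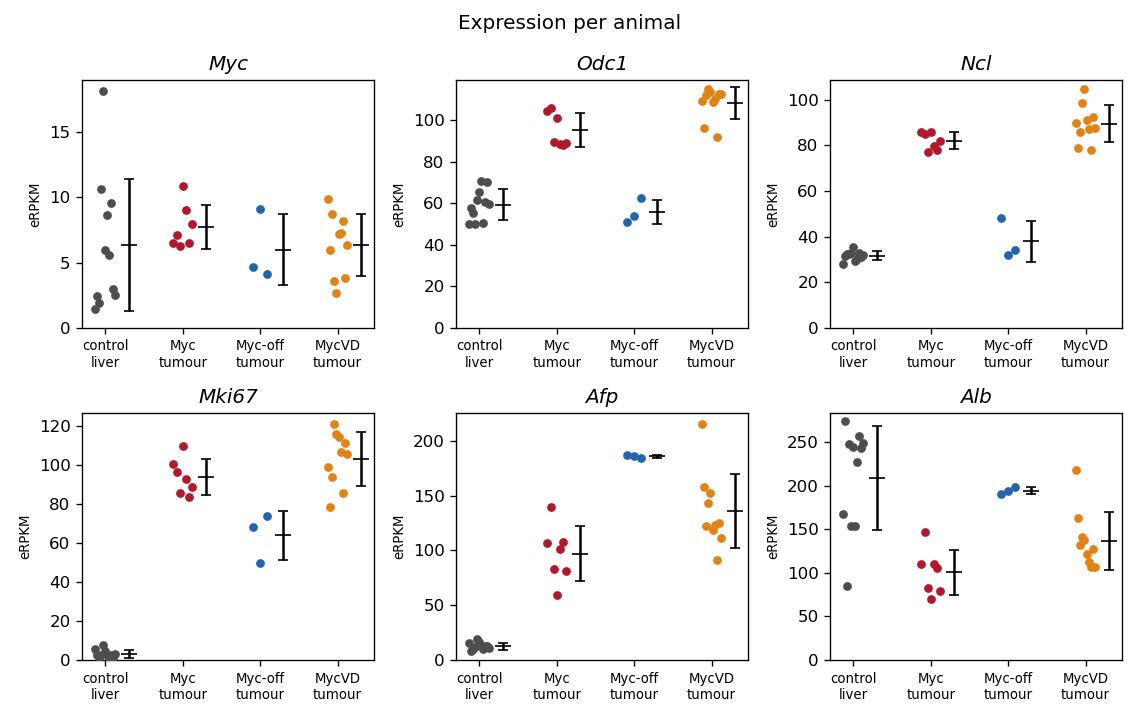
Expression in eRPKM (vertical axes, from 0) of Myc, Odc1, Ncl, Mki67, Afp and Alb in the 4 groups, with 1 point per animal ID and a bar for the mean ± SD. Odc1 averaged 95.3 ± 8.17 in Myc tumours and 55.8 ± 5.94 after switch-off, whereas Afp averaged 97.1 ± 25.4 and 186 ± 1.29.

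Myc-off tumours were compared with Myc tumours to find genes that depend on continued transgene expression. Odc1 fell to 55.8 ± 5.94 eRPKM (n = 3) from 95.3 ± 8.17 (n = 7), a log2 fold change of -0.77 ± 0.10 (adjusted p = 1.8e-07), and Ncl stood at 38.0 ± 8.97 against 82.0 ± 3.72, a change of -1.14 ± 0.09 (adjusted p = 9.8e-12). Max fell by 0.72 ± 0.13 (adjusted p = 3.7e-05). Afp rose by 0.92 ± 0.22 (adjusted p = 8.3e-04). Alb rose by 0.92 ± 0.26 (adjusted p = 3.7e-03), a call that was lost with quantile normalisation and with a depth term. Afp and Alb both lay near the read ceiling after switch-off, which limits the size of these changes. Mki67 stood at 64.0 ± 12.5 against 93.8 ± 9.17, a change of -0.57 ± 0.32 that did not pass the threshold (adjusted p = 0.14) but passed it with every tumour as its own sample. Of 14566 genes 7348 passed the threshold, 3236 higher and 4112 lower after 16 hours of switch-off, and 2588 changed at least 2-fold. The share of higher calls was 44.0%, but 49.6% under median-ratio scaling and 51.3% of 6674 with a depth term, so most calls being falls was not stable.

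The largest falls without overlap of ID means were Hpdl at -5.84 ± 0.24, the carbonic anhydrase gene Car12 at -5.59 ± 0.16, the nuclear receptor gene Nr1h5 at -4.66 ± 0.19, Lingo3 at -4.64 ± 0.26 and Camkv at -4.19 ± 0.48. The largest such rises were the tight junction gene Cldn6 at 4.30 ± 0.88, the cytochrome P450 gene Cyp2a12 at 4.05 ± 0.62, the surface antigen gene Psca at 4.03 ± 0.32, the choline transporter family gene Slc44a4 at 3.94 ± 0.57 and the pantetheinase gene Vnn1 at 3.89 ± 0.66. Cdkn1a stood at 0.20 ± 0.46 (adjusted p = 0.75), or -0.01 without Myc-off ID150584 and -0.15 with array weights, and Myc at -0.43 ± 0.49 (adjusted p = 0.50). Cdkn2b rose by 1.12 ± 0.30 (adjusted p = 2.5e-03), and stood at 0.55 (adjusted p = 0.13) without Myc-off ID151964. Zbtb17 fell by 0.54 ± 0.16 (adjusted p = 5.2e-03), a call that was lost with a depth term.

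Growth genes fell together within 16 hours. All 53 ribosome biogenesis genes fell, 52 of them under median-ratio scaling, with a median log2 fold change of -1.52 (53 adjusted over the list alone, limma's camera adjusted p = 1.1e-31; adjusted p = 0.099 with an estimated correlation). The ribosome assembly genes Nle1 at -2.76 ± 0.18 and Rrp12 at -2.67 ± 0.24 led the list. Of 31 known Myc-activated genes 24 fell and 0 rose, with a median of -0.72 (24 and 0 adjusted over the list alone, adjusted p = 6.9e-08; adjusted p = 0.22 with an estimated correlation). The DNA polymerase delta gene Pold2 at -2.08 ± 0.18 and the branched-chain amino acid transaminase gene Bcat1 at -2.04 ± 0.34 led the list. Of 35 DNA replication genes 34 fell and 0 rose, with a median of -1.46 (34 and 0 adjusted over the list alone, adjusted p = 3.7e-11; adjusted p = 0.27 with an estimated correlation). The polymerase epsilon gene Pole at -2.50 ± 0.29 and Mcm10 at -2.32 ± 0.22 led the list. Of 30 mitosis genes 29 fell and 0 rose, with a median of -1.43 (29 and 0 adjusted over the list alone, adjusted p = 8.8e-14; adjusted p = 0.23 with an estimated correlation). The checkpoint kinase genes Bub1b at -2.23 ± 0.22 and Ttk at -2.21 ± 0.19 led the list.

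Hepatocyte genes rose after switch-off. All 35 plasma protein genes rose, 30 of them under quantile normalisation, 33 after the start position correction and 34 without the shallowest Myc-off library, with a median log2 fold change of 0.84 (35 adjusted over the list alone, limma's camera adjusted p = 2.6e-13; adjusted p = 0.23 with an estimated correlation). The coagulation factor gene F11 at 3.83 ± 0.42 and C9 at 3.79 ± 0.46 led the list. Of 31 drug metabolism genes 30 rose and 0 fell, with a median of 1.80 (30 and 0 adjusted over the list alone, adjusted p = 2.0e-08; adjusted p = 0.30 with an estimated correlation). Cyp2a12 and Cyp2f2 at 4.05 ± 0.62 and 3.88 ± 0.70 led the list. Of 20 acute phase genes 13 rose and 0 fell, with a median of 1.44 (13 and 0 adjusted over the list alone, adjusted p = 2.5e-04; adjusted p = 0.33 with an estimated correlation). The serum amyloid genes Saa1 at 3.64 ± 1.02 and Saa2 at 3.64 ± 0.92 led the list. Saa1 stood at 2.82 (adjusted p = 0.051) without Myc-off ID151964. Of 16 genes reported as repressed by Myc with Miz1, 9 rose and 0 fell, with a median of 0.51 (9 and 0 adjusted over the list alone, adjusted p = 0.016; adjusted p = 0.22 with an estimated correlation). Clu at 2.50 ± 0.43 and the transcription factor gene Cebpd at 1.14 ± 0.30 led the list. Of 9 cholangiocyte markers 6 rose and 0 fell, with a median of 1.36 (6 and 0 adjusted over the list alone, adjusted p = 0.010; adjusted p = 0.27 with an estimated correlation). The keratin gene Krt7 at 3.79 ± 0.73 and the cell adhesion gene Epcam at 3.01 ± 0.70 led the list. The comparison rests on 3 Myc-off IDs, which are numbered above all other IDs, and leaving out 1 ID at a time gave 6151 to 7287 calls.

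The genes that moved in opposite directions in these 2 comparisons describe the part of the tumour pattern that went back within 16 hours. Of 7278 genes higher in Myc tumours than in control liver, 3664 (50.3%) were lower after switch-off and 465 higher. The strongest were Car12 (6.05 ± 0.11, then -5.59 ± 0.16), Hpdl (5.50 ± 0.17, then -5.84 ± 0.24), Lingo3 (5.11 ± 0.18, then -4.64 ± 0.26), Camkv (4.81 ± 0.34, then -4.19 ± 0.48) and Ccnb1ip1 (6.34 ± 0.23, then -4.13 ± 0.33). Of 4362 genes lower in Myc tumours, 2287 (52.4%) were higher after switch-off and 144 lower. The strongest were Cyp2a12 (-5.79 ± 0.44, then 4.05 ± 0.62), Cyp2f2 (-6.73 ± 0.49, then 3.88 ± 0.70), F11 (-4.71 ± 0.30, then 3.83 ± 0.42), C9 (-5.56 ± 0.33, then 3.79 ± 0.46) and the urate pathway gene Urad (-5.23 ± 0.45, then 3.74 ± 0.64). Both comparisons contain the Myc tumours. With no effect the simulated counts averaged 0, which was fixed in advance because almost no gene is then called. Independent lists would share 2055 and 969 genes, and splitting the Myc tumour IDs between the comparisons gave medians of 3126 and 1820. The covariance of the fold changes was -0.79, against -0.02 in the simulation, and their correlation -0.63, against -0.39.

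**Figure D2:**
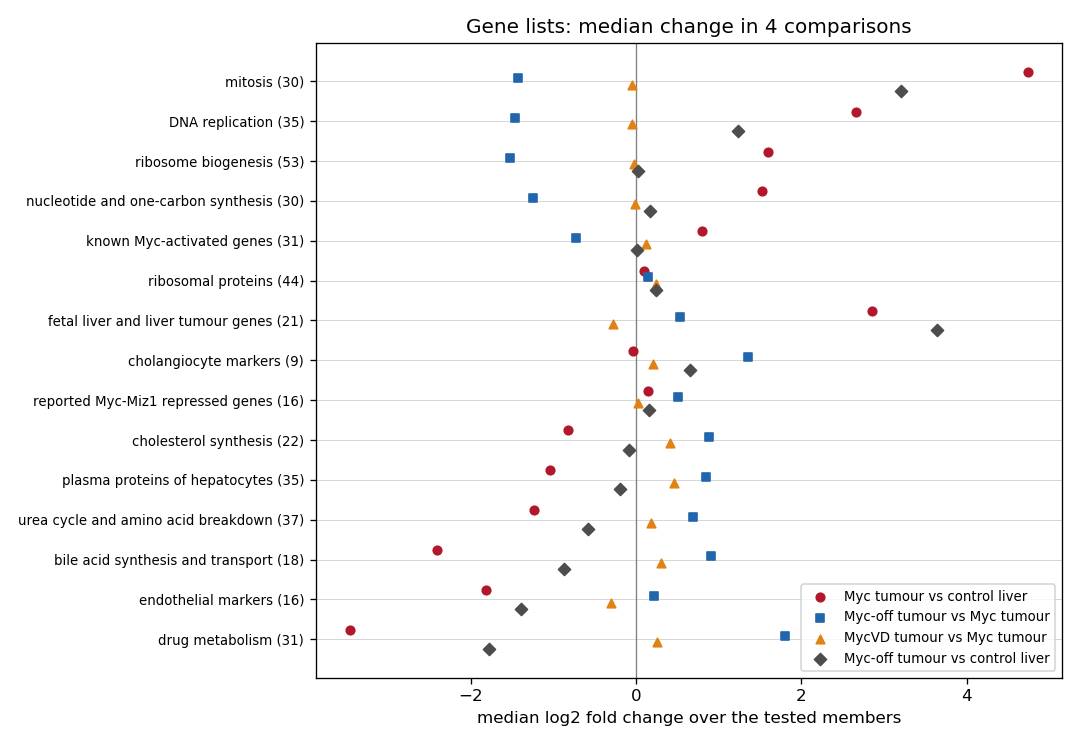
Median log2 fold change over the tested members (horizontal axis) of 15 gene lists, with the number of members beside each name; red circles are Myc tumours against control liver, blue squares Myc-off against Myc tumours, orange triangles MycVD against Myc tumours and grey diamonds Myc-off tumours against control liver. Mitosis genes lay at 4.74, -1.43, -0.05 and 3.20 in these comparisons, and drug metabolism genes at -3.46, 1.80, 0.26 and -1.78.

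MycVD tumours were compared with Myc tumours to find genes that differ when Myc binds Miz1 less well. All MycVD IDs are numbered above all Myc tumour IDs, so a difference in date or batch cannot be told apart from the substitution. Krt20, a keratin gene of gut epithelium, was at 17.9 ± 9.61 eRPKM in MycVD tumours (n = 10) and 1.497 ± 0.905 in Myc tumours (n = 7), a log2 fold change of 3.17 ± 0.28 (adjusted p = 6.4e-09). Other large rises were Fam83f at 2.73 ± 0.39, the serpin gene Serpina12 at 2.55 ± 0.41, the carboxylesterase gene Ces1e at 2.42 ± 0.29 and C9 at 2.40 ± 0.33. Large falls were the pancreatic colipase gene Clps at -3.80 ± 0.41, the muscle creatine kinase gene Ckm at -2.99 ± 0.42, Lin28b, which encodes an RNA-binding protein of fetal tissues, at -2.92 ± 0.65 and the kinase gene Stk39 at -2.78 ± 0.27. The difference was the smallest of the 5 comparisons by calls, with 2290 genes, 955 higher and 1335 lower, and 401 of them at least 2-fold.

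Among the genes named in every comparison, Mki67 stood at 0.13 ± 0.23 (adjusted p = 0.74) and Ncl at 0.12 ± 0.06 (adjusted p = 0.19), which turned to -0.04 and -0.02 with quantile normalisation. Odc1 stood at 0.19 ± 0.07 (adjusted p = 0.072). Max stood at -0.23 ± 0.09 (adjusted p = 0.10), which passed the threshold with quantile normalisation among others, and Myc at -0.33 ± 0.35 (adjusted p = 0.57). Zbtb17 stood at -0.18 ± 0.11 (adjusted p = 0.28) and Cdkn1a at -0.17 ± 0.33 (adjusted p = 0.77), which turned to 0.09 and 0.33 with a depth term. Odc1 passed the threshold without Myc tumour ID125324 (0.21, adjusted p = 0.046), MycVD ID133079 (0.21, adjusted p = 0.049) or MycVD ID134660 (0.21, adjusted p = 0.036). Alb stood at 0.46 ± 0.19 (adjusted p = 0.088) and at 0.56 (adjusted p = 0.041) without Myc tumour ID125324.

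Plasma protein genes were higher in MycVD tumours: 23 of 35 rose and 0 fell (29 rose when adjusted over the list alone), with a median log2 fold change of 0.46 (limma's camera adjusted p = 6.1e-19; adjusted p = 0.22 with an estimated correlation). C9 and Fetub, which encodes fetuin-B, at 1.01 ± 0.29 led the list. Fetub stood at 0.81 (adjusted p = 0.063) without Myc tumour ID130395. The MycVD libraries were shallower than those of the Myc tumours, and with a depth term 8 plasma protein genes rose and the median was 0.21, while the list test still passed (adjusted p = 3.9e-08). Of 22 cholesterol synthesis genes 11 rose and 0 fell (13 rose when adjusted over the list alone), with a median of 0.41 (adjusted p = 1.3e-08; adjusted p = 0.29 with an estimated correlation). The mevalonate pathway gene Mvd at 1.17 ± 0.27 and the sterol reductase gene Tm7sf2 at 0.81 ± 0.17 led the list. Of 16 male-biased liver genes 5 rose and 0 fell, with a median of 0.62 (5 and 0 adjusted over the list alone, adjusted p = 9.7e-05; adjusted p = 0.35 with an estimated correlation). The major urinary protein genes Mup20 at 2.93 ± 0.68 and Mup3 at 2.40 ± 0.66 led the list. MycVD ID134660 was the highest of its group for both, at 82.8 and 58.0 eRPKM. Of 21 genes of the Atf4 amino acid and stress response 6 fell and 0 rose (10 fell and 1 rose when adjusted over the list alone), with a median of -0.40 (adjusted p = 6.9e-04; adjusted p = 0.28 with an estimated correlation). The stanniocalcin gene Stc2 at -2.54 ± 0.40 and the glutathione-degrading enzyme gene Chac1 at -2.36 ± 0.47 led the list.

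Of 16 genes reported as repressed by Myc with Miz1, 3 were higher and 1 lower in MycVD tumours, with a median log2 fold change of 0.03 (3 and 1 adjusted over the list alone, limma's camera adjusted p = 0.18; adjusted p = 0.37 with an estimated correlation). Clu rose by 1.86 ± 0.31 (adjusted p = 1.0e-04). Cdkn2b rose by 0.66 ± 0.21 (adjusted p = 0.035), but missed the threshold at 0.59 to 0.67 (adjusted p 0.053 to 0.065) without any 1 of Myc tumour ID125320, ID128992, ID125324, ID130395, ID128285 and ID126948 or MycVD ID133763, ID133765 and ID133761. Vamp4, a gene of vesicle fusion, was at -0.31 ± 0.10 (adjusted p = 0.034), and missed it at -0.31 to -0.28 (adjusted p 0.053 to 0.078) without any 1 of ID128992, ID126947, ID130395, ID128285 and ID126948 or ID133764, ID133765 and ID134668. Of 21 fetal liver and liver tumour genes 5 fell and 1 rose (7 fell when adjusted over the list alone), with a median of -0.28 (adjusted p = 0.24; adjusted p = 0.67 with an estimated correlation). Beside Lin28b, the RNA-binding protein gene Igf2bp1 was at -2.19 ± 0.75 (adjusted p = 0.044), and at -2.24 to -1.86 (adjusted p 0.057 to 0.088) without any 1 of ID125320, ID128992, ID125324, ID130395, ID128285 and ID126948 or ID133762, ID133763, ID133764, ID133765, ID134664 and ID134668. Afp rose by 0.51 ± 0.16 (adjusted p = 0.027), and stood at 0.48 (adjusted p = 0.057) without ID126947, 0.47 (adjusted p = 0.066) without ID130395 and 0.40 (adjusted p = 0.081) without ID126948. Of 44 ribosomal protein genes 13 rose and 0 fell (31 rose when adjusted over the list alone), with a median of 0.24 (adjusted p = 9.1e-13; adjusted p = 0.34 with an estimated correlation), but the median was 0.04 and 0 members rose with quantile normalisation. Rpl6 rose by 0.29 ± 0.09 (adjusted p = 0.033) and missed the threshold at 0.25 to 0.28 (adjusted p 0.052 to 0.082) without any 1 of ID128992, ID126947, ID130395, ID128285, ID126948, ID133074, ID133762 and ID133763. Rplp0 rose by 0.28 ± 0.10 (adjusted p = 0.045) and missed it at 0.24 to 0.28 (adjusted p 0.054 to 0.11) without any 1 of these or of ID133764 and ID134664.

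The number of calls between MycVD and Myc tumours moved with the processing: it was 4791 with array weights, 3987 without the 8 libraries with low Gapdh, 1097 with a depth term and 1487 without Myc tumour ID130395. Of the 2290 calls 41.7% were higher as deposited, against 53.1% of 2141 under median-ratio scaling and 64.0% with a depth term, where Lin28b, Mup20 and Mup3 also missed the threshold.

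Whether genes repressed in Myc tumours are less so with MycVD was asked gene by gene. Of 4362 genes lower in Myc tumours than in control liver, 668 (15.3%) were higher in MycVD than in Myc tumours and 149 lower. The strongest were Mup20 (-5.36 ± 0.66, then 2.93 ± 0.68), Serpina12 (-3.67 ± 0.40, then 2.55 ± 0.41), Ces1e (-5.64 ± 0.29, then 2.42 ± 0.29), Mup3 (-7.16 ± 0.64, then 2.40 ± 0.66) and C9 (-5.56 ± 0.33, then 2.40 ± 0.33). Of 7278 genes higher in Myc tumours, 996 (13.7%) were lower in MycVD tumours and 121 higher. Among the strongest were Clps (5.35 ± 0.40, then -3.80 ± 0.41), the secreted neuronal protein gene Lgi2 (4.79 ± 0.48, then -3.16 ± 0.49), Ckm (4.62 ± 0.42, then -2.99 ± 0.42) and the laminin gene Lama1 (3.16 ± 0.47, then -2.97 ± 0.48). With no effect the simulated counts averaged 0, which was fixed in advance because almost no gene is then called. Independent lists would share 286 and 667 genes. With the Myc tumour IDs split between the comparisons the median counts were 200 and 188, below those of independent lists, but these fits had fewer Myc tumour IDs. A simulated difference common to all tumours gave means of 0 and 0.45 genes, but there MycVD and Myc tumours were alike, so counts of about 0 were again fixed in advance. The covariance was -0.24, with a median of -0.22 when the IDs were split, against -0.02 in the simulation without effect. The correlation of the fold changes was -0.39, against a mean of -0.58 in that simulation, -0.07 with a simulated difference common to all tumours, and a median of -0.35 with the IDs split. The 668 genes became 1027 without the low Gapdh libraries and 434 among genes under 400 reads per kb. The 996 became 1750 without those libraries, 288 with a depth term and 622 without Myc tumour ID130395.

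MycVD tumours were also compared with control liver. Mki67 was at 103 ± 13.7 eRPKM (n = 10) against 3.22 ± 2.09 (n = 11), a log2 fold change of 4.97 ± 0.20 (adjusted p = 3.5e-20), and Ncl and Odc1 rose by 1.48 ± 0.06 and 0.87 ± 0.06. Afp rose by 3.36 ± 0.14, Cdkn1a by 3.25 ± 0.29, Max by 0.98 ± 0.08 and Cdkn2b by 0.96 ± 0.19, and Alb was at -0.58 ± 0.16 (adjusted p = 2.1e-03), a call that was lost with quantile normalisation. Myc stood at 0.26 ± 0.31 (adjusted p = 0.44) and Zbtb17 at 0.16 ± 0.10 (adjusted p = 0.13), which turned to -0.12 and -0.15 with quantile normalisation. The largest rises were Ggt1 at 6.73 ± 0.13, Dusp9 at 6.52 ± 0.18, Bex2 at 6.52 ± 0.19, the protease inhibitor gene A2m at 6.33 ± 0.21 and Shbg, which encodes the sex hormone carrier of plasma, at 6.24 ± 0.17. The largest falls were Ces3b at -6.90 ± 0.38, Ces1f at -6.56 ± 0.33, the cytochrome P450 gene Cyp2d13 at -6.41 ± 0.33, Dio1 at -6.35 ± 0.37 and Slco1a1 at -6.32 ± 0.47. Of 14566 genes 11686 passed the threshold, 7156 higher and 4530 lower, and 4903 changed at least 2-fold. Under median-ratio scaling the share of higher calls went from 61.2% to 51.0% and the median of all genes from 0.22 to 0.03.

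All 30 mitosis genes rose in MycVD tumours against control liver, with a median log2 fold change of 4.71 (30 adjusted over the list alone, limma's camera adjusted p = 1.3e-16; adjusted p = 0.22 with an estimated correlation). Ccnb1 at 5.77 ± 0.20 and the checkpoint kinase gene Bub1 at 5.50 ± 0.11 led the list. Most erythroid, neutrophil and T and NK cell markers also rose, although those list tests did not pass. Which cells carried the mitosis transcripts was not tested. All 53 ribosome biogenesis genes rose, with a median of 1.54 (53 adjusted over the list alone, adjusted p = 2.7e-15; adjusted p = 0.23 with an estimated correlation). Rrp1b at 3.39 ± 0.08 and Gar1, a gene of small nucleolar ribonucleoproteins, at 2.44 ± 0.09 led the list. All 31 drug metabolism genes fell, with a median of -3.60 (31 adjusted over the list alone, adjusted p = 2.6e-13; adjusted p = 0.23 with an estimated correlation). Cyp1a2 at -6.05 ± 0.41 and Ugt3a2 at -5.98 ± 0.35 led the list. Of 35 plasma protein genes 33 fell and 0 rose, with a median of -0.67 (33 and 0 adjusted over the list alone, adjusted p = 2.1e-09; adjusted p = 0.30 with an estimated correlation). Azgp1 at -4.46 ± 0.53 and F11 at -3.72 ± 0.27 led the list.

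The calls of the 2 tumour types against control liver were largely shared. Higher in both were 6603 genes and lower in both 3999, together 10602, and 18 moved in opposite directions. The largest shared rises, as Myc and then MycVD tumours, were AF357359 (7.38 ± 0.62 and 6.79 ± 0.56), Ggt1 (6.53 ± 0.15 and 6.73 ± 0.13), Dusp9 (6.54 ± 0.20 and 6.52 ± 0.18), A2m (6.29 ± 0.24 and 6.33 ± 0.21) and Bex2 (6.27 ± 0.21 and 6.52 ± 0.19). The largest shared falls were Ces3b (-7.78 ± 0.42 and -6.90 ± 0.38), Ces1f (-7.50 ± 0.37 and -6.56 ± 0.33), Cyp2d13 (-6.85 ± 0.36 and -6.41 ± 0.33), Dio1 (-7.22 ± 0.41 and -6.35 ± 0.37) and Slco1a1 (-7.35 ± 0.52 and -6.32 ± 0.47). Both comparisons use the same control IDs. Unchanged groups gave a simulated mean of 0 shared calls, which was fixed in advance because almost no gene is then called. Independent lists would share 4932, and splitting the control IDs between the comparisons gave a median of 9838. The covariance of the fold changes was 1.99, against 0.01 in the simulation, and their correlation 0.96, against 0.44. A simulated difference common to all tumours gave means of 11269 shared calls, a covariance of 2.24 and a correlation of 0.99, all above the observed values.

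Myc-off tumours were compared with control liver to see what remained different after 16 hours. Mki67 was at 64.0 ± 12.5 eRPKM (n = 3) against 3.22 ± 2.09 (n = 11), a log2 fold change of 4.28 ± 0.30 (adjusted p = 2.7e-13), and Afp was at 186 ± 1.29 against 12.8 ± 3.15, a change of 3.76 ± 0.21 (adjusted p = 9.5e-16). Cdkn1a rose by 3.62 ± 0.44, Cdkn2b by 1.42 ± 0.28 and Max by 0.49 ± 0.12. Odc1 stood at -0.08 ± 0.10 (adjusted p = 0.48), or 0.08 with quantile normalisation. Alb stood at -0.12 ± 0.25 (adjusted p = 0.70), Zbtb17 at -0.19 ± 0.15 (adjusted p = 0.28) and Myc at 0.16 ± 0.46 (adjusted p = 0.78), the last turning to -0.28 with quantile normalisation and -0.15 without Myc-off ID151964. Alb and Afp lay near the read ceiling in Myc-off tumours, and Alb also in some control IDs. Similar Alb values therefore do not show equal levels. Under median-ratio scaling Odc1 and Zbtb17 passed the threshold at -0.26 and -0.36. Ncl rose by 0.22 ± 0.09 (adjusted p = 0.025), and stood at 0.05 (adjusted p = 0.61) without Myc-off ID150584. The largest rises were AF357359 at 8.40 ± 0.83, A2m at 7.05 ± 0.32, AF357355 at 6.73 ± 0.75, Ggt1 at 6.62 ± 0.20 and Bex2 at 6.59 ± 0.28. The largest falls were Ces3b at -6.51 ± 0.57, Slco1a1 at -6.45 ± 0.70, the acetyltransferase family gene Cml2 at -6.32 ± 0.59, Ces1f at -6.21 ± 0.50 and Mup17 at -5.92 ± 0.36.

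All 30 mitosis genes were still higher in Myc-off tumours than in control liver, with a median log2 fold change of 3.20 (30 adjusted over the list alone, limma's camera adjusted p = 2.1e-23; adjusted p = 0.18 with an estimated correlation). Ccnb1 at 4.38 ± 0.30 and Mki67 led the list. Most erythroid, neutrophil and T and NK cell markers were also higher, and which cells carried the mitosis transcripts was not tested. Of 35 DNA replication genes 31 rose and 2 fell (32 rose when adjusted over the list alone), with a median of 1.23 (adjusted p = 8.5e-06; adjusted p = 0.46 with an estimated correlation). Mcm6 and Gins2 rose by 3.01 ± 0.42 and 2.76 ± 0.39, and Mcm10, needed to start replication forks, was at -2.12 ± 0.21. Of 53 ribosome biogenesis genes 14 rose and 9 fell, and the median of 0.02 turned to -0.16 under median-ratio scaling, while the mean was 0.07 and the list test pointed down (14 and 9 adjusted over the list alone, adjusted p = 0.75; adjusted p = 0.96 with an estimated correlation). The RNA polymerase I gene Polr1a rose by 1.01 ± 0.10 and the snoRNP gene Nop58 by 0.93 ± 0.12, and the ribosome assembly gene Bop1 was at -0.80 ± 0.13. Of 21 fetal liver and liver tumour genes 18 rose and 0 fell, with a median of 3.64 (18 and 0 adjusted over the list alone, adjusted p = 2.5e-07; adjusted p = 0.099 with an estimated correlation). Bex2 and Bex1 at 6.34 ± 0.29 led the list. Of 20 p53 target genes 16 rose and 1 fell, with a median of 0.76 (16 and 1 adjusted over the list alone, adjusted p = 5.4e-03; adjusted p = 0.38 with an estimated correlation). Cdkn1a and the pro-apoptotic gene Pmaip1 at 3.27 ± 0.27, with Ei24 at -1.01 ± 0.09 led the list. Of 31 drug metabolism genes 27 fell and 0 rose, with a median of -1.78 (27 and 0 adjusted over the list alone, adjusted p = 8.4e-10; adjusted p = 0.27 with an estimated correlation). Ugt3a2 at -5.01 ± 0.52 and Cyp4f14 at -4.76 ± 0.69 led the list. In all 8434 genes passed the threshold, 5290 higher and 3144 lower, and 3463 changed at least 2-fold. Under median-ratio scaling the share of higher calls went from 62.7% to 48.1% and the median of all genes from 0.15 to -0.02.

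Tumours of the same animal ID were compared to see how far they are separate samples. Over 9 IDs with several tumours the within-animal correlation estimated with limma was 0.30 ± 0.04 (jackknife SE), and 0.27 to 0.31 without any 1 ID. The median SD over genes, in log2 units, was 0.227 between tumours of 1 animal and 0.233 between animals of a group. The first is of single tumours and the second of means over the tumours of an ID, which lowers it. Their closeness therefore does not show that animals differ no more than tumours of 1 animal. Of the Myc tumour libraries 5 had low Gapdh and the same IDs as others without it. Without all libraries with low Gapdh the correlation was 0.28 over 7 IDs, and both SDs were 0.220. This alternative was chosen after the data were seen.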

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

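The 3 patterns weighed here, and the tests of their possible causes, were chosen after the results were seen. What each cause would predict was written down after the pattern was seen and before the value of its test was computed. Another pattern, the excess of higher over lower genes in Myc tumours, had been picked first. It was replaced by the third one below, found among the outlying animals, after median-ratio scaling had brought it to 51.5%.

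Animal IDs were regrouped 100 times to ask how often a chance division gives as many calls. The counts of 11640, 7348, 2290, 11686 and 8434 genes were each reached in 1 of 100 groupings, the real one, with highest other counts of 7449 for Myc tumours against control liver, 2371 for Myc-off against Myc tumours, 1546 for MycVD against Myc tumours, 7206 for MycVD tumours against control liver and 4195 for Myc-off tumours against control liver. The overlaps of 3664, 2287, 10602, 668 and 996 genes were each reached in 1 of 100 groupings, with a highest other count of 0. Any overlap above 0 would have stood out in this way, so it says nothing about their size. Of 175 gene list tests 97 passed the threshold, a number reached in 15 of 100 groupings, with a highest other count of 110. Chance is therefore not excluded for the number of list tests, and the counts of list members were not regrouped. A rule of this kind would by chance pick out about 1 in 20 groups.

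Plasma protein genes were higher in MycVD than in Myc tumours, with a median log2 fold change of 0.46 over 35 genes. The greater depth of the Myc tumour libraries may account for part of it, since a depth term left 0.21 ± 0.12 (jackknife SE), under the 0.229 set as the criterion by less than 1 SE, although the list test still passed (limma's camera, adjusted p = 3.9e-08). A distinct class of libraries with low Gapdh was argued against by 0.47 ± 0.10 without these libraries. After a correction per library for reads lost at shared start positions the median was 0.53 ± 0.16. That correction assumed 2000 start positions per kb, while the highest value of a library could be as low as 1461 reads per kb. It may therefore remove too little of the read ceiling, which stays open as the way in which depth would act. Depth differs between the groups, so a depth term can also take away part of a real difference. Open stay an effect of the V394D substitution, a difference in date or batch, the share of hepatocytes and tumour stage, which were not tested.

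Cholangiocyte markers were higher after switch-off, with a median log2 fold change of 1.36 over 9 genes. More bile duct cells in the sampled tissue could explain this, and 6 of 9 markers rose, among them Krt7 and Epcam, which does not tell it from a change within tumour cells. Between late and early controls (4 and 7 IDs) the median of these markers was -0.35 ± 0.15, which argues against such a rise over the span of the controls. The late controls are numbered below all Myc-off IDs, so a drift or batch difference in the range of the Myc-off animals is not excluded. Krt7 and Epcam were also near the floor in control liver, at 0.70 and 0.74 eRPKM. Limma called 0 genes between these controls, but 3659 had an unadjusted p under 0.05 where 728 would be expected with no difference, so a drift of other genes is not excluded. A change of tumour cells towards a bile duct state stays open.

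Liver genes were far higher in MycVD ID134660 than in the other MycVD tumours: over 140 of them it lay a median of 11.1% (quartiles 6.04 to 22.0) of the way from the median of the other animals of its group to the mean of control liver, against at most 3.36% for any other MycVD animal and 2.11% for any Myc tumour animal. These genes had at least 20 eRPKM in control liver and were at least 20-fold above the median of the other MycVD animals. The low shares of those animals are therefore partly fixed by the choice. Non-tumour liver in the sampled tissue may explain it, as 10 endothelial markers lay a median of 19.7% ± 11.2 (jackknife SE over markers, not animals, range 13.4 to 140) of the same way. Kept were markers with at least 1 eRPKM in control liver and at least 2-fold above the median of the other MycVD animals. Pecam1, Cdh5, Tie1 and Esam were thereby left out. The share was not computed for any other animal, so it has no reference and does not decide the question. The markers Clec4g and Oit3 had been seen before and were also left out. A deviation in the scaling of the library was argued against by a median log2 difference of 0.0418 over 2415 genes at similar levels in control liver and the other MycVD animals, against 2.70 over the liver genes. A tumour of a more differentiated kind stays open.

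Single animal IDs were tested in the Myc and MycVD groups only, as groups of 3 or of more than 10 IDs, here Myc-off tumours and control liver, were not screened. Of 200 tests among the named genes 32 stood apart, 26 in MycVD and 6 in Myc tumours. Dixon's test was used at 95% confidence on eRPKM without a log scale, which favours flags of high values. Some flags arise by chance at this limit, and the 6 in Myc tumours may all do so. Values are in eRPKM, with the range of the other IDs of the group. In ID134660, of the MycVD group, 15 genes were the highest. They were Azgp1 at 64.1 (0.291 to 28.6), C9 at 44.9 (4.94 to 25.2), Ces1f at 10.5 (0.0499 to 3.03), Ces3a at 62.8 (0.373 to 17.1), Ces3b at 11.1 (0 to 2.56), Clec4g at 16.9 (0.155 to 4.31), Cml2 at 39.2 (0.728 to 12.1) and Cyp1a2 at 28.0 (0.202 to 6.47). The others were Cyp2d13 at 11.7 (0.147 to 4.16), Cyp4f14 at 24.0 (0.0575 to 10.0), Mup20 at 82.8 (0.562 to 29.6), Mup3 at 58.0 (0 to 18.7), Oit3 at 6.24 (0.295 to 2.34), Slco1a1 at 33.5 (0.0631 to 4.53) and Ugt3a2 at 14.7 (0.0644 to 3.48).

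In ID133074, also of the MycVD group, Alb was at 217 (106 to 163), Clps at 5.99 (0 to 2.68), Saa1 at 47.0 (0 to 19.4) and Saa2 at 46.5 (0.157 to 19.9), and Dusp9 was the lowest at 69.1 (86.2 to 104). Other MycVD values were Peg10, the lowest, at 3.75 (90.3 to 152) and Shbg at 92.4 (20.8 to 56.2) in ID133762, Chac1 at 3.12 (0 to 1.28) in ID134664, Igf2bp2 at 1.53 (0.0572 to 0.403) and Lama1 at 18.5 (0.0929 to 9.78) in ID133079, and Serpina12 at 34.0 (2.12 to 17.4) in ID133764. Among Myc tumours Ccnd2 was at 11.8 (8.09 to 9.67) in ID130395, Krt20 at 3.44 (0.739 to 1.71) in ID126947, Mup17 at 0.381 (0 to 0.0714) and Mup3 at 6.19 (0.0421 to 2.002) in ID126948, and Slco1a1 at 2.51 (0.0120 to 0.894) and Ugt3a2 at 1.71 (0 to 0.459) in ID125324.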

How the results depend on the processing

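The alternatives were chosen in advance except 7, which were added after the results had been seen: the start position correction, genes under 400 reads per kb, voom, both treatments of the low Gapdh libraries, leaving out the shallowest Myc-off library and the depth term. The members followed for each list were also chosen after a first round of alternatives. Over 100 named genes in 191 gene and comparison pairs, 6860 values were computed: 6686 kept their call, 123 were weaker, 33 stronger, 16 moved and 2 reversed. With the members that the same rule picks from every list, 499 pairs gave 18025 values, of which 7 reversed.

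Zbtb17: Myc tumour vs control liver reversed to -0.0430 with quantile normalisation and to -0.0705 with a depth term, from 0.35. Among list members that are not named elsewhere, the folate enzyme gene Shmt1 went from -0.34 to 0.10 with quantile normalisation in Myc tumours against control liver. The elongation factor gene Eef2 went from 0.34 to -0.11 with quantile normalisation and to -0.06 with a depth term in Myc-off against Myc tumours, and from 0.23 to -0.01 with either in MycVD against Myc tumours.

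With a 2-fold minimum the calls were 5406 for Myc tumours against control liver, 2588 for Myc-off against Myc tumours, 401 for MycVD against Myc tumours, 4903 for MycVD tumours against control liver and 3463 for Myc-off tumours against control liver. MycVD against Myc tumours gave 4791 with array weights, 3987 without the low Gapdh libraries and 1097 with a depth term, against 2290. The 668 genes lower in Myc tumours and higher in MycVD tumours became 434 among genes under 400 reads per kb and 1027 without the low Gapdh libraries. The 996 genes higher in Myc and lower in MycVD tumours became 1750 without those libraries and 288 with a depth term. Of 175 list tests 97 passed with the preset correlation and 0 with an estimated correlation. For these moved counts the cause was not tested.

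Leaving out 1 ID at a time gave 11394 to 11752 calls for Myc tumours against control liver, 6151 to 7287 for Myc-off against Myc tumours, 1487 to 2604 for MycVD against Myc tumours, 11588 to 11845 for MycVD tumours against control liver and 7288 to 8686 for Myc-off tumours against control liver. It gave 10464 to 10736 shared calls and 93 to 99 list tests. Genes up in Myc tumours and down after switch-off numbered 3210 to 3797, and genes down and then up 1880 to 2392. Genes lower in Myc and higher in MycVD tumours numbered 489 to 738, and genes higher in Myc and lower in MycVD tumours 622 to 1156. The lowest counts of 1487 and 622 came without Myc tumour ID130395, and the cause was not tested.

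No paired analysis was possible because replicate numbers pair no samples across the groups. The shallowest library had 3.25 M reads, which limits the precision of low genes, and the read ceiling limits that of abundant ones.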

Other observations

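The test for sex was added after the sexes had been read from the data, and the genes and lists below were picked after their values were seen. The genes were not followed through the alternatives. Against control liver, of 12 erythroid genes 11 rose and 0 fell in Myc tumours (11 rose when adjusted over the list alone), with a median log2 fold change of 2.50, although limma's camera did not pass the threshold (adjusted p = 0.078; adjusted p = 0.71 with an estimated correlation). It did not pass in MycVD tumours either, where 10 rose and 0 fell (10 rose when adjusted over the list alone), with a median of 2.29 (adjusted p = 0.082; adjusted p = 0.71 with an estimated correlation). In Myc-off tumours 10 rose and 0 fell (11 rose when adjusted over the list alone), with a median of 2.47 (adjusted p = 6.4e-03; adjusted p = 0.55 with an estimated correlation). Of 12 neutrophil markers 10 rose and 0 fell in Myc-off tumours against control liver (10 rose when adjusted over the list alone), with a median of 3.20 (adjusted p = 8.7e-03; adjusted p = 0.59 with an estimated correlation). In Myc tumours 9 rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 2.75, but the list did not pass (adjusted p = 0.23; adjusted p = 0.79 with an estimated correlation). In MycVD tumours 10 rose and 0 fell (10 and 0 adjusted over the list alone), with a median of 2.95, and it did not pass either (adjusted p = 0.068; adjusted p = 0.71 with an estimated correlation). Of 13 T and NK cell markers 10 rose and 0 fell in Myc-off tumours (11 rose when adjusted over the list alone), with a median of 1.13 (adjusted p = 0.015; adjusted p = 0.37 with an estimated correlation). In Myc tumours 8 rose and 0 fell (7 rose when adjusted over the list alone), with a median of 0.66 (adjusted p = 0.30; adjusted p = 0.73 with an estimated correlation). In MycVD tumours 8 rose and 0 fell (8 rose when adjusted over the list alone), with a median of 0.67 (adjusted p = 0.47; adjusted p = 0.79 with an estimated correlation). Median-ratio scaling took the erythroid list past the threshold in Myc tumours (adjusted p = 0.031) and MycVD tumours (adjusted p = 0.036) and the neutrophil list in MycVD tumours (adjusted p = 0.024). By contrast, quantile normalisation ended the T and NK call in Myc-off tumours (adjusted p = 0.16).

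Some genes differed from control liver by sex. With a term for sex and its interaction, limma called 81 genes in Myc tumours against control liver (954 at an unadjusted p under 0.05) and 91 in MycVD tumours against control liver (1622 unadjusted), and 0 of the named genes. In Myc tumours, with 4 female and 3 male IDs, the sulfotransferase genes Sult2a5 and Sult3a1 fell by 4.62 and 7.60 in females and stood at -0.00 and -0.86 in males. The fatty acid elongase gene Elovl3 stood at -3.52 in females and -7.10 in males, and Cyp4a12a at -0.56 and -4.41. Sult3a1 belongs to the list of female-biased liver genes, and Elovl3 and Cyp4a12a to that of male-biased ones. Such differences can come from unlike levels in control liver of the 2 sexes, which were not compared, and do not show a tumour response that depends on sex. In Myc tumours the neutrophil granule gene Ngp rose by 4.89 in females and 2.32 in males. The neutrophil markers S100a8, S100a9, Ltf, Elane, Mpo and Mmp9 were also called there, each with a higher fold change in females. Neither Ngp nor these markers were called in MycVD tumours.

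Sfmbt2 ran from 0.0807 to 0.352 eRPKM in control libraries, 0.287 to 5.64 in Myc tumours, 0.334 to 25.5 in Myc-off tumours and 0.405 to 80.2 in MycVD tumours. The Y-linked gene Ddx3y was at 36.1 eRPKM in tumour A of Myc tumour ID128992 and at 7.91 in tumour B, while Eif2s3y was at 32.0 and 37.5, Kdm5d at 15.4 and 13.7 and Uty at 17.5 and 17.1. Gapdh ran from 14.96 to 64.6 eRPKM in control libraries, 16.1 to 68.1 in Myc tumours, 40.9 to 99.2 in Myc-off tumours and 19.8 to 61.4 in MycVD tumours.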
